A study of Homo sapiens with 6 samples.

How the data were processed

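Total RNA of 6 MCF7 samples was measured on Illumina beadarrays. Per the labels, the RNA was extracted with a Qiagen kit and labelled with Cy3 by Illumina's protocol. The deposited table holds, for each of 48701 probes and each sample, an intensity on a linear scale, and the submitters' processing notes name BeadStudio without a version. How it summarised the beads, and whether it subtracted background, is not given in the sources used here. The deposited bead files, 2 for each sample, hold 65535 single-bead intensities each with a numeric bead code, per the file headers. For 259 of 360 bright codes the mean of the beads of both files of a sample, after beads over 3 median absolute deviations from the median were left out, lay within 0.01 on the log2 scale of a table row in every sample, and for 0 of 360 with the beads of 1 file alone. For these codes the table thus held a mean over both bead files of a sample. Its array medians and 5th percentiles differ, so neither quantile normalization nor scaling to a common median had been applied. All per-sample columns of the table were used.

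Samples were grouped by their titles. The table as used here holds no detection p-values and no labelled control probes, so the plan for such a table was followed and background correction from either was not run. Signals were set to at least 1, converted to log2 and quantile normalized (limma 3.58.1 in R 4.3.3), with no background correction in the main setting, so log2 fold changes of dim probes are understated. Probes whose mean lay above the lowest quartile of all probes were tested, 36525 in number. Figures were drawn with matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15.

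Gene names came from the platform annotation, in which 23687 probes had 1 gene symbol, 35 had several and 24979 were not listed and stay unnamed here. Of the first, 23651 matched a current gene identifier of the RefSeq annotation of GRCh38.p14, which was used for names only. They cover 18774 genes, 16766 of them tested. A gene is represented by its tested probe with the highest mean signal. Of 2756 genes with several tested probes, 903 had a probe called for DZNep with the replicate block, and 33 of these had called probes in both directions.

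Each comparison was a contrast of group means in 1 limma fit of all 6 samples (lmFit and eBayes with an intensity trend, prior degrees of freedom 5.32), so that the 3 groups share 1 estimate of the spread. P-values are two-sided, adjusted by Benjamini and Hochberg over all probes tested, and called at an adjusted p under 0.05. The labels number the replicates 1 and 2 in each group. The differences between replicates 1 and 2 correlated between groups at r = 0.72 (untreated with 5-Aza-CdR), 0.58 (untreated with DZNep) and 0.58 (5-Aza-CdR with DZNep), all above 0.1, so same-numbered samples deviated together, and this was settled before calls were compared. The fit with the replicate number as a block (prior degrees of freedom 11.7) was planned as an alternative and is given beside results that it changes. The design text also names 2 harvest days and 4 technical repeats per treatment, which the labels do not tie to samples.

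Before the data were examined, 26 gene lists were fixed (755 genes, 678 with a probe, 650 tested): PRC2 and other histone methyltransferases, DNA methylation machinery, methionine cycle and polyamines, nucleoside uptake and activation, germline and cancer-testis genes, interferon response and antigen presentation, p53 targets, cell cycle and mitosis, DNA replication and nucleotide synthesis, oestrogen receptor targets, luminal breast markers, basal and mesenchymal markers, leukocyte and stromal markers, developmental PRC2 target genes, integrated stress response, unfolded protein response, cholesterol synthesis and uptake, metallothioneins and oxidative stress, apoptosis regulators, cell adhesion and extracellular matrix, imprinted genes, histone genes, ribosomal proteins, oxidative phosphorylation, glycolysis and hypoxia, and reference genes. Lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, adjusted over 26 lists and 3 comparisons, and again with an estimated correlation and with fry. The groups, designs, lists, the rule for named genes and most alternatives were chosen before the data were examined.

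The rule for named genes took, for each drug, the 10 genes with the largest rise and the 10 with the largest fall among called genes whose treated samples both lay beyond both untreated samples, filled up by lowest p where fewer passed. For the direct comparison it took 5 of each. It added up to 4 members of each list with the lowest p, 13 measured genes whatever their values (EZH2, SUZ12, AHCY, DNMT1, DNMT3A, DNMT3B, UHRF1, DCK, CDKN1A, ESR1, TXNIP, FBXO32 and TFF1; EED had no listed probe), and up to 5 genes called with both drugs in the same and in opposite directions. The text gives a selection of the list members. Keratin genes outside the lists were named after their values were seen.

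Alternatives were median scaling, no further normalization, normexp background correction with offsets of 16 and 50, no filter on dim probes, only probes above the median, no intensity trend, no moderation of the spread (a plain t-test), only the 2 groups compared, a minimum change of 1 on the log2 scale, the mean of all probes of a gene, the replicate block and leaving out each sample in turn. A sample left alone in its group was then assumed to vary like the other groups. The planned filter on probes detected in all 6 samples could not be run without detection values, and the planned quantile normalization without background correction is the main setting. Alternatives on single bead files used the 2347 codes present in all files with enough signal. The files stop at the lowest codes and pair no code with a gene, so they gave counts of codes only.

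The tests were tried on simulated data of 36525 probes with 200 changed ones, 50 at each size. For DZNep against untreated the fit without the block recovered 16% of changes of 0.5, 66% of changes of 1 and 100% of changes of 2 and 3 on the log2 scale, with 0.704% of calls false; with the block it recovered 86% of changes of 0.5 and 100% of the others, with 4.93% false. For 5-Aza-CdR against untreated the values were 22%, 70%, 98% and 100% with 0.685% false, and 82% and 100% with 3.54% false. With each probe's own moderated variance in the simulation, 14.8% of blocked calls for 5-Aza-CdR were false and 7.14% for DZNep. Each simulated change was equal in both treated samples, whereas 90.7% of genes called for DZNep with the block changed less in replicate 2. The recovery without the block therefore does not carry over to DZNep, where 0 probes passed although SNAI2 stood at 2.65. Bootstrap intervals came from 1000 resamples of genes and cover the choice of genes only.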

Results

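Gene expression was measured in MCF7 cells, an established human breast cancer line that expresses the oestrogen receptor and has a luminal phenotype. The series held 6 samples in 3 groups of 2: untreated cells, cells given 5-Aza-CdR at 1 µM for 72 h, and cells given DZNep for 72 h at a dose that the labels do not give. 5-Aza-CdR (decitabine) is a deoxycytidine analogue that is built into DNA and traps DNA methyltransferases there. DZNep (3-deazaneplanocin A) is an adenosine analogue that inhibits S-adenosylhomocysteine hydrolase and so limits enzymes that take methyl groups from S-adenosylmethionine, among them EZH2, the histone methyltransferase of Polycomb repressive complex 2 (PRC2). RNA of each sample was read on an Illumina beadarray with 48701 probes. Median signals were 105 to 112 in the replicate 1 samples and 131 to 136 in the replicate 2 samples, and the 5th percentile of the signals, near the background, was 73.8 to 80.3 and 102 to 106. The number of samples limits the precision. Nothing in the labels says that the replicates came from separate cultures, and the design text speaks of technical repeats, so the p-values measure the spread between these samples, which may be technical.

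DZNep treatment and replicate number separated the samples, and each 5-Aza-CdR sample lay near the untreated sample of its number. The first principal component of 36525 probes, with 49.97% of the variance, placed the DZNep samples at 28.3 and 32.2 and the other 4 samples between -26.8 and -0.71. On that component untreated and 5-Aza-CdR replicate 2 (-6.94 and -0.71) lay closer to the DZNep samples than untreated and 5-Aza-CdR replicate 1 (-26.1 and -26.8). The second component, with 30.4% of the variance, placed the replicate 1 samples between 10.2 and 26.5 and the replicate 2 samples between -21.0 and -11.6. Results are therefore given from the limma fit without the replicate number and, where it changed a call, from the fit with the replicate number as a block. Log2 fold changes are given ± the standard error (SE) of the fit without the block, with n = 2 samples per group.

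**Figure D1:**
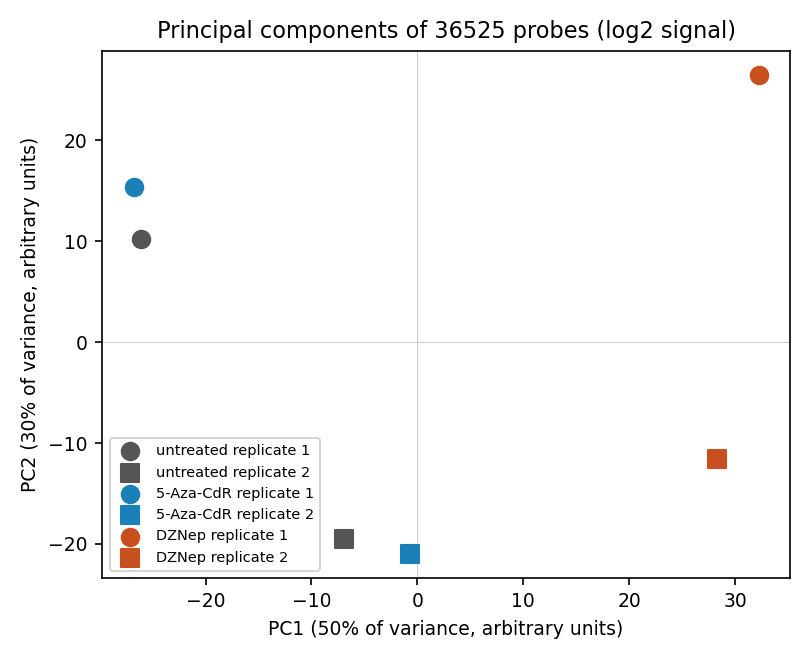
Position of the 6 samples on the first and second principal components of the normalized log2 signals of 36525 probes, in arbitrary units. DZNep samples lie to the right, and circles (replicate 1) lie above squares (replicate 2) on the second component.

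The comparison of DZNep with untreated cells asked which transcripts differ after 72 h with the hydrolase inhibitor. Of 42 measured interferon and antigen presentation genes, 27 rose and 2 fell in the fit with the replicate number as a block, among those that rose the ubiquitin-like modifier ISG15, at 1.37 ± 0.20 on the log2 scale, and the antiviral protein gene IFIT3, at 1.65 ± 0.28. SNAI2, a transcription factor of epithelial-mesenchymal transition, stood at 2.65 ± 0.49. Of 31 measured DNA replication genes 22 fell and 0 rose in that fit, among them PRIM1, the catalytic subunit of DNA primase, at -1.19 ± 0.23, and the oestrogen receptor gene ESR1 stood at -0.85 ± 0.16. All 5 genes passed in that fit (adjusted p = 5.79e-05 to 0.00019), and none passed in the fit without it, where the lowest adjusted p of all probes was 0.0622.

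With the block, 5076 of 36525 probes changed, 2453 upward and 2623 downward, and covered 3833 different genes. Of these probes 226 rose and 154 fell at least 2-fold. Without the block limma called 0 probes, although 4505 had an unadjusted p under 0.05, against 1826 expected by chance, and a fit without moderation of the spread also called 0 after adjustment. That 0 became 734 on the authors' values with no further normalization (293 higher, 441 lower), 609 with only the untreated and DZNep samples in the fit, 610 without 5-Aza-CdR replicate 1, 635 without 5-Aza-CdR replicate 2 and 1 without untreated replicate 2. The blocked count fell to 1240 without untreated replicate 1, 2643 without untreated replicate 2 and 2832 without DZNep replicate 1, and on the values with no further normalization its split was 1564 higher and 4150 lower (27.4% higher, against 48.3%). On those values the median log2 fold change of all probes was -0.07.

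The changes within replicate 1 and within replicate 2 correlated across 16766 genes (Pearson's r = 0.887, Spearman's rho = 0.755; genes are not independent replicates). In 3277 of the 3614 genes whose main probe was called with the block (90.7%), the change was smaller within replicate 2.

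**Figure D2:**
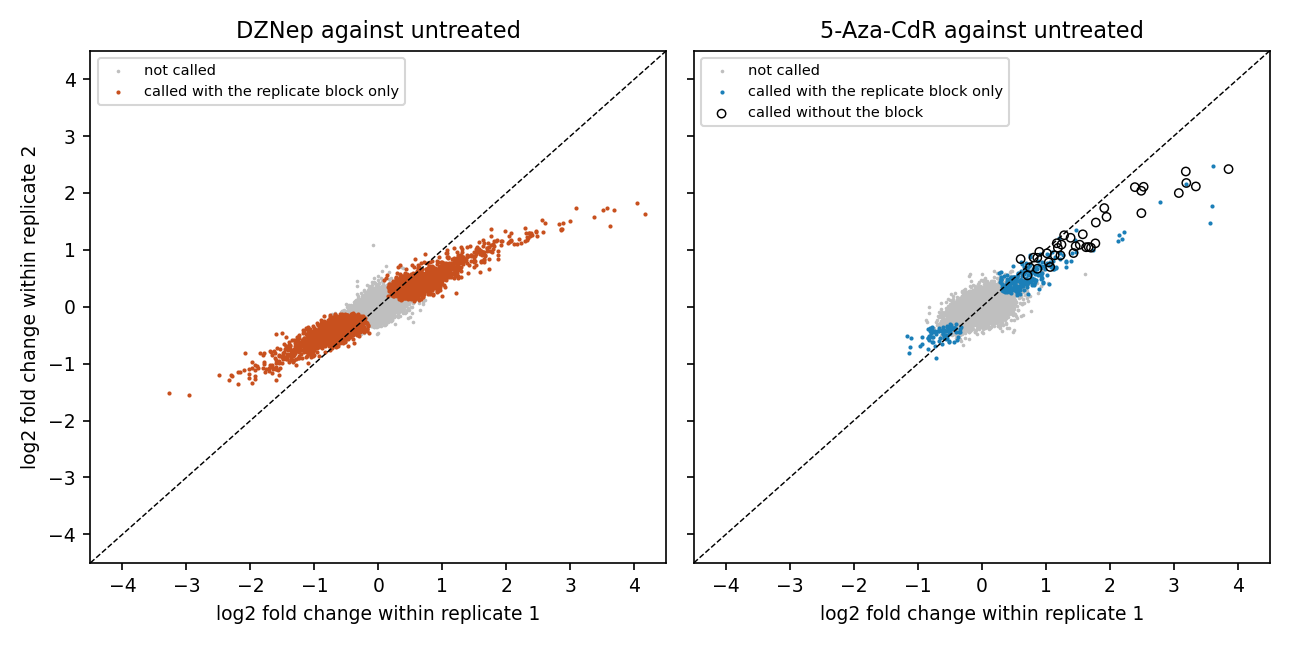
Log2 fold change against untreated within replicate 1 (horizontal axis) and within replicate 2 (vertical axis) for each tested gene, for DZNep and for 5-Aza-CdR. Coloured points passed with the replicate number as a block, open circles without it, and most DZNep points of large change lie nearer the horizontal axis than the dashed line of equal change.

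The 10 named genes with the lowest p among those higher after DZNep all had an adjusted p of 0.0622 without the block and passed with it (adjusted p = 5.41e-05 to 0.000142). They included genes of the actin cytoskeleton and of focal adhesions, CSRP1 at 1.29 ± 0.15 and ZYX, which encodes zyxin, at 1.36 ± 0.19. TRIM29, a tripartite motif gene, stood at 1.83 ± 0.25, LAMB3, a laminin chain of epithelial basement membranes, at 0.88 ± 0.12, ANXA8 at 1.01 ± 0.13, EMP1 at 1.06 ± 0.13 and FGFBP1 at 0.89 ± 0.12. GABBR2 (1.07 ± 0.14), CLEC3A (0.75 ± 0.09) and the chemokine gene CXCL8 (0.58 ± 0.08) completed them. The 10 with the lowest p among those lower also had an adjusted p of 0.0622 without the block and 5.41e-05 to 8.99e-05 with it. AGR2, a disulfide isomerase gene expressed with the oestrogen receptor in breast cancer, stood at -1.60 ± 0.22, and GFRA1, a receptor for glial cell line-derived neurotrophic factor, at -1.37 ± 0.18. COL21A1 (-1.47 ± 0.19), ADCY1 (-1.42 ± 0.18), MLPH (-1.19 ± 0.15), CCM2L (-1.10 ± 0.15), GNG4 (-1.07 ± 0.15), ACOX2 (-0.97 ± 0.13), KATNAL2 (-0.72 ± 0.08) and SLC47A1 (-0.67 ± 0.09) completed them. Other tested probes of ANXA8 and LAMB3 did not pass, but were dim (mean log2 signals 7.02 to 7.22), where changes are understated.

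Of the 26 gene lists fixed before the data were examined, 9 shifted with DZNep by camera with its preset correlation. No member of any list passed without the block when adjusted over all probes. Of all 16766 tested genes, by their brightest probe, 1707 rose and 1907 fell with the block, against which the member counts below are to be read. Calls were more frequent among bright probes: 5178 of 24350 passed in a blocked fit of probes above the median signal, against 5076 of 36525. Lists of bright genes can thus exceed the share over all genes without a shift of their own. The interferon and antigen presentation list was higher (median 0.50, adjusted p = 9.77e-10), but not with an estimated correlation (adjusted p = 0.346 with an estimated correlation). Of its 42 measured genes 27 rose and 2 fell with the block, and 24 were higher and 1 was lower without it when adjusted over the list alone. Examples are OAS1 (1.30 ± 0.21) and OASL (1.43 ± 0.23), of the oligoadenylate synthetase family. Of 27 p53 targets (median 0.30, adjusted p = 0.000654, and adjusted p = 0.346 with an estimated correlation), 12 rose and 2 fell with the block, and 6 and 1 passed without it adjusted over the list alone. TP53INP1 (1.08 ± 0.19), GADD45A, a stress-induced growth arrest gene (1.05 ± 0.21), and FBXO32, an F-box gene (2.25 ± 0.44, with 1 of its 3 probes not passing), were among those that rose. The basal and mesenchymal markers were higher (median 0.16, adjusted p = 0.00777, and adjusted p = 0.346 with an estimated correlation): 8 of 23 rose and 2 fell with the block, and 6 and 1 passed without it adjusted over the list alone, with KRT15, a basal keratin, at 2.69 ± 0.63 and ACTA2, smooth muscle actin, at 1.90 ± 0.37.

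The replication list was lower (median -0.43, adjusted p = 1.43e-08, and adjusted p = 0.346 with an estimated correlation), with 22 of 31 genes falling and 0 rising with the block and 7 lower without it adjusted over the list alone. CDC45, a part of the replicative helicase, stood at -1.20 ± 0.22, POLA2 at -1.09 ± 0.23 and MCM7 at -0.41 ± 0.11. The cell cycle list was lower (median -0.32, adjusted p = 1.33e-07, and adjusted p = 0.346 with an estimated correlation): 18 of 38 genes fell and 0 rose with the block, and 11 were lower without it adjusted over the list alone. AURKB, a mitotic kinase (-0.93 ± 0.20), and the cyclin genes CCNE2 (-0.92 ± 0.20) and CCNB2 (-0.73 ± 0.15) fell. Of 29 oestrogen receptor targets (median -0.24, adjusted p = 0.00321, and adjusted p = 0.346 with an estimated correlation), 14 fell and 5 rose with the block, and 12 were lower and 4 higher without it adjusted over the list alone. PGR, the progesterone receptor gene, stood at -0.89 ± 0.16, PKIB at -1.56 ± 0.25 and SERPINA1 at -1.36 ± 0.23. The cholesterol synthesis and uptake list was lower (median -0.30, adjusted p = 0.000299, and adjusted p = 0.346 with an estimated correlation), with 8 of 24 genes falling and 0 rising with the block and 4 lower without it adjusted over the list alone. Its members FADS1, a fatty acid desaturase (-1.76 ± 0.28), and FASN, fatty acid synthase (-0.53 ± 0.11), act in fatty acid rather than sterol synthesis. For MCM7, CCNE2, PKIB and SERPINA1, 1 other tested probe each did not pass. Those of CCNE2, PKIB and SERPINA1 were dim (mean log2 signals 6.78 to 7.10).

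The integrated stress response list was higher (median 0.18, adjusted p = 0.0132, and adjusted p = 0.459 with an estimated correlation), with 9 of 27 genes rising and 2 falling with the block and 6 and 1 passing without it adjusted over the list alone. DDIT4, an inhibitor of mTORC1 signalling, stood at 1.87 ± 0.30 and PHGDH, of serine synthesis, at -1.10 ± 0.18. The developmental PRC2 target genes had a median of 0.04 (adjusted p = 0.0209, and adjusted p = 0.346 with an estimated correlation): 9 of 61 rose and 1 fell with the block, 7 and 1 passed without it adjusted over the list alone, and 51 did not pass. Those that rose included CDKN2B, a cyclin-dependent kinase inhibitor (1.44 ± 0.27), SOX9 (1.10 ± 0.21) and TBX3 (0.53 ± 0.10, on 1 of its probes), and LHX2 fell (-1.15 ± 0.19). None of the 9 shifts passed with an estimated correlation. Those estimates ran from -0.00658 (p53 targets) to 0.151 (interferon) without the block, against the preset 0.01. Where they were higher, the preset p-values may be too low. In simulated data with independent noise a shifted list had an unadjusted p of 0.00263 to 0.00771 by that camera test with the block. Adjustment turned 0.00366 (germline genes, 5-Aza-CdR, without the block) into 0.286, so a miss there does not exclude a shift. With fry the p53, cell cycle, replication and basal lists passed (adjusted p = 0.0494 for each). The others of the 9 did not pass with fry (0.0737 to 0.266). The shift of the developmental list did not pass without the filter on dim probes (adjusted p = 0.0901), without untreated replicate 2 (0.118) or without DZNep replicate 1 (0.0964), nor that of the stress response list without untreated replicate 1 (0.103) or DZNep replicate 2 (0.102).

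Enzymes that the drugs act on or through were read whatever their values. EZH2 stood at -0.62 ± 0.33 after DZNep (adjusted p = 0.555 without the block, 0.00615 with it; -0.34 without untreated replicate 1), and SUZ12, another PRC2 subunit, at -0.13 ± 0.20 (0.932 and 0.546). AHCY, which encodes the hydrolase that DZNep inhibits, stood at 0.13 ± 0.23 (0.944 and 0.476). UHRF1, which recruits the maintenance DNA methyltransferase, stood at -0.90 ± 0.17 (0.0635 and 0.000257), and DNMT1, that methyltransferase, at -0.34 ± 0.15 (0.411 and 0.0126; -0.19 without DZNep replicate 1). DNMT3B (-0.07 ± 0.15) and DCK, the kinase that activates 5-Aza-CdR (-0.28 ± 0.17), did not pass in either fit. Probes disagreed for DNMT3A and for CDKN1A, a p53-induced cell cycle inhibitor: their brightest probes (0.01 ± 0.16 and -0.03 ± 0.10) passed in neither fit, and a dimmer probe of each passed with the block (0.43, adjusted p = 0.00168, and 0.63, adjusted p = 0.000614). TXNIP, a thioredoxin inhibitor, stood at 0.34 ± 0.17 and passed with the block (adjusted p = 0.0247; 0.16 without DZNep replicate 2 and 0.51 without DZNep replicate 1). TFF1, an oestrogen-induced secreted peptide gene, had signals of 42360 to 48360, near the top of the range, and stood at -0.08 ± 0.07. EED, the third core PRC2 subunit, had no listed probe.

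The other 17 lists did not shift by camera, and without the block each had 0 to 6 genes higher and 0 to 5 lower when adjusted over the list alone. The apoptosis regulators came closest (median 0.18, adjusted p = 0.050 without the block, above the threshold before rounding, and 0.0281 with it, where adjusted p = 0.55 with an estimated correlation), with 7 of 25 genes rising and 2 falling with the block, such as TNFSF10, which encodes the death ligand TRAIL, at 1.02 ± 0.18. They passed without the block under median scaling (0.0244), without the filter (0.0438) and without untreated replicate 2 (0.0296), 5-Aza-CdR replicate 1 (0.0265), 5-Aza-CdR replicate 2 (0.0321) or DZNep replicate 2 (0.0371). Of 36 adhesion and matrix genes (adjusted p = 0.125 by camera, but 0.0494 with fry), 10 rose and 4 fell with the block, among them TGFBI (1.5 ± 0.23) and IGFBP3 (1.77 ± 0.33). Of 26 glycolysis and hypoxia genes (0.55), 6 rose and 4 fell, with NDRG1 at 1.69 ± 0.27 and PFKP at -1.06 ± 0.21, while its second probe rose (1.49, adjusted p = 5.86e-05 with the block). Of 23 metallothionein and oxidative stress genes (0.308), 5 rose and 2 fell, with HMOX1, haem oxygenase, at 0.87 ± 0.17. Of 18 unfolded protein response genes (0.589), 4 rose and 5 fell, with the chaperone HSPA5 at 1.78 ± 0.47 and the transcription factor XBP1 at -0.98 ± 0.14. Of 17 nucleoside uptake and activation genes (0.137), 1 rose and 6 fell, with RRM2, a ribonucleotide reductase subunit, at -1.04 ± 0.30. Of 18 methionine cycle and polyamine genes (0.29), 3 rose and 5 fell, with CTH at 0.77 ± 0.17 and CBS at -0.71 ± 0.16.

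In the PRC2 and histone methyltransferase list 2 of 24 genes rose and 3 fell with the block (adjusted p = 0.55 by camera without it), with PHF19 at -0.90 ± 0.18 and NSD1 at 0.62 ± 0.19 (0.36 without DZNep replicate 1), while another NSD1 probe fell (-0.45, adjusted p = 0.00952 with the block). In the DNA methylation machinery 1 of 12 rose and 4 fell (0.552), in the ribosomal proteins 2 of 25 rose and 6 fell (0.3, and 0.00552 under median scaling), and in oxidative phosphorylation 1 of 26 rose and 2 fell (0.803). Of 45 germline genes 2 rose and 1 fell (0.3), of 16 imprinted genes 1 rose (0.803), and of 13 reference genes 2 rose and 1 fell (0.546). The leukocyte and stromal markers, of cells that a pure line should lack, had 2 of 15 genes rising and 1 falling (0.0932, and 0.0456 without DZNep replicate 1), with VWF at 1.00 ± 0.33 (0.66 without untreated replicate 1) and the haemoglobin gene HBA1 at -0.45 ± 0.18 (-0.23 without DZNep replicate 1). Median, mean and test differed in sign for the histone genes (median 0.23, mean -0.0006, 0.947), the luminal markers (median 0.05, mean -0.07, 0.803) and the imprinted genes (median -0.01, mean 0.11). With the block 5 of 15 histone genes rose and 4 fell, such as H4C3 at -0.69 ± 0.10, and 3 of 21 luminal markers rose and 4 fell, such as ELF3 at 0.91 ± 0.19. Camera's sign turned under median scaling for the histone, reference and oxidative phosphorylation lists.

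**Figure D3:**
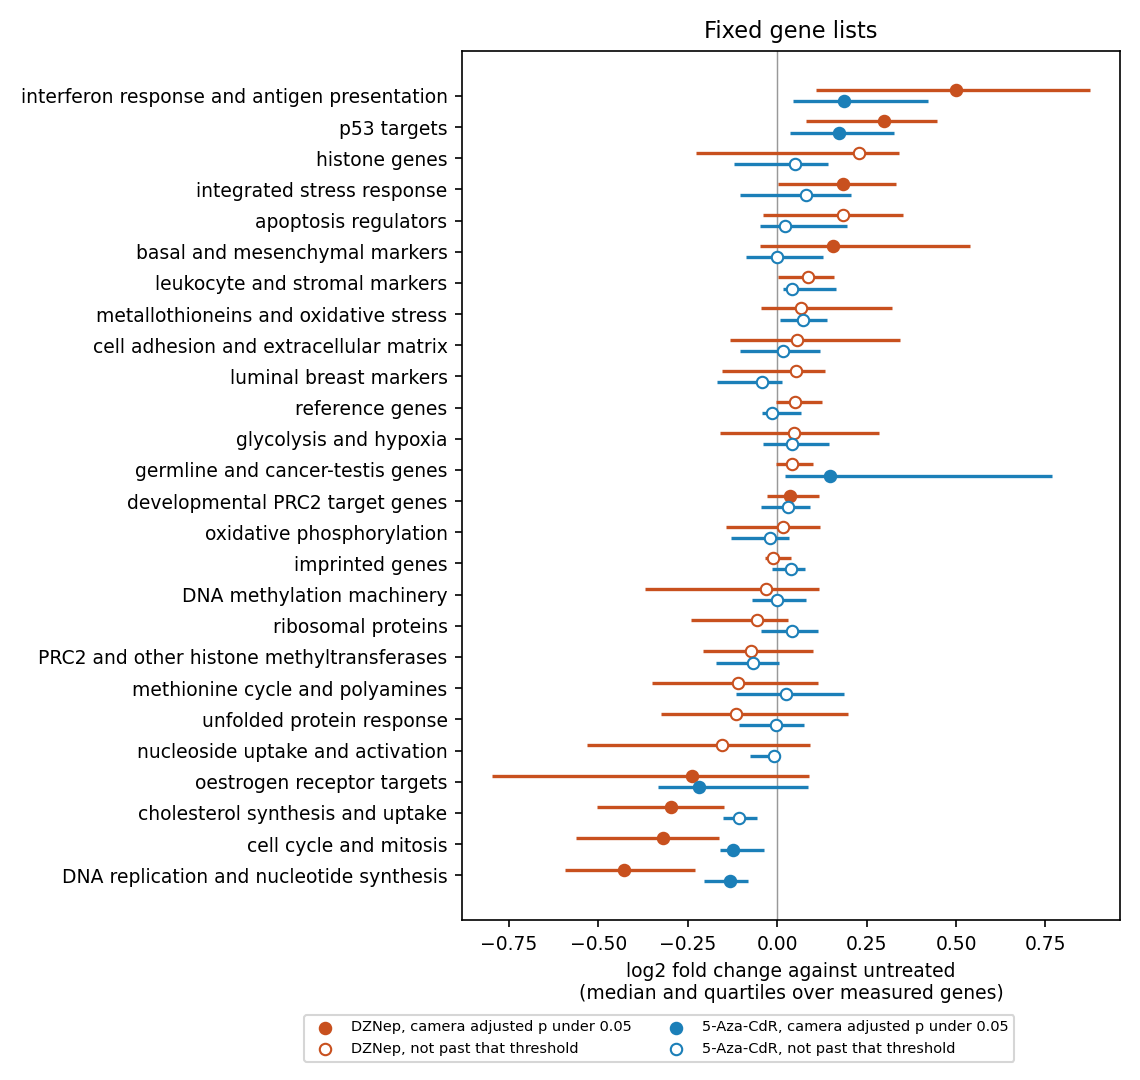
Median log2 fold change against untreated of the measured genes of each fixed list, with lines from the lower to the upper quartile, for DZNep and 5-Aza-CdR. Filled points passed camera with the preset correlation at an adjusted p of 0.05, and none passed with an estimated correlation.

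The comparison of 5-Aza-CdR with untreated cells asked which transcripts differ after 72 h with the DNA methyltransferase trap. Of 45 measured germline and cancer-testis genes, normally expressed in germ cells and in tumours, 11 rose without the block and 17 with it, and 28 passed in neither fit. Among those that rose, PAGE2B rose by 2.27 ± 0.25 from a mean signal of 125 (adjusted p = 0.0232) and MAGEA8 by 1.76 ± 0.16 (0.0164). Outside the list GCNA, a germ cell nuclear protein gene, rose by 2.25 ± 0.24 (0.0229). INA, a neuronal intermediate filament gene, rose by 3.14 ± 0.43 (0.0440), from a mean signal of 128 to 1123, and NLRP2, a NOD-like receptor gene expressed in oocytes, by 2.73 ± 0.32 (0.0253).

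Without the block 55 of 36525 probes passed, all of them higher, for 40 named genes and 10 probes without a listed name. Of these 38 rose at least 2-fold. In all, 1159 probes had an unadjusted p under 0.05, against 1826 expected by chance. With the block 438 probes passed, 331 higher and 107 lower, for 356 genes, and 76 rose and 0 fell at least 2-fold. Without untreated replicate 1 or without 5-Aza-CdR replicate 1 the count of 55 fell to 0, without untreated replicate 2 it fell to 6, and a fit without moderation, a fit without the intensity trend and a fit on gene means each gave 0. The blocked count was 147 without untreated replicate 1, 212 without untreated replicate 2, 729 without 5-Aza-CdR replicate 2, 1198 without DZNep replicate 1 and 1196 without DZNep replicate 2. The changes within the replicate numbers correlated at r = 0.624 and rho = 0.352 across genes.

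The 10 genes with the largest rise were taken among those called without the block. Of these, VCX (2.69 ± 0.32), CT45A3 (2.32 ± 0.30), PAGE2B and PAGE5 (1.82 ± 0.14) belong to X-linked cancer-testis families of near-identical copies, so the copy that rose is uncertain. SNAR-A1, a small noncoding RNA of a multicopy family, rose by 2.07 ± 0.25 from a signal of 3235, and the processed pseudogene SUMO1P1 by 2.54 ± 0.31. GPX1, glutathione peroxidase, rose by 2.78 ± 0.31 on 1 probe, while its other tested probe stood at -0.03 and was dim (mean log2 signal 6.75). Genes lower after 5-Aza-CdR passed only with the block. Those with the lowest p were ELOVL2, a fatty acid elongase (-0.91 ± 0.18, adjusted p = 0.239 without the block and 0.00122 with it), CLSTN2 (-0.71 ± 0.14), KLF12 (-0.47 ± 0.09), SH3BP2 (-0.42 ± 0.09), MGP, matrix Gla protein (-0.47 ± 0.10), UGT2B17, a steroid glucuronidation enzyme (-0.63 ± 0.13), PLAC1 (-0.71 ± 0.15), RAMP3 (-0.98 ± 0.22), SLC47A1 (-0.39 ± 0.09) and GFRA1 (-0.80 ± 0.18), with adjusted p from 0.239 to 0.426 without the block and up to 0.0189 with it. For CT45A3, PAGE5, KLF12 and UGT2B17, 1 other tested probe each did not pass. These other probes were dim (mean log2 signals 6.72 to 7.33).

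Of all 16766 tested genes, by their brightest probe, 37 rose and 0 fell after 5-Aza-CdR without the block, and 260 rose and 81 fell with it. The germline and cancer-testis list shifted upward (median 0.15, camera adjusted p = 5.78e-21, adjusted p = 0.286 with an estimated correlation and 0.0494 with fry). Of its 62 genes 45 were measured, that is, had a probe past the signal filter. Of these, 11 rose without the block and 17 rose with it, 0 fell in either, and 17 rose without the block when adjusted over the list alone. The filter took the mean over all 6 samples, so a gene can enter through its 5-Aza-CdR signals, and these shares may be too high. Near-identical copies count as separate genes. CTAG1B, which encodes the NY-ESO-1 antigen and has a near-identical copy, rose by 0.86 ± 0.09 on 1 of its probes. The interferon list was higher (median 0.19, adjusted p = 4.01e-06, and adjusted p = 0.346 with an estimated correlation): 6 of 42 genes rose with the block, 0 passed without it and 1 passed adjusted over the list alone. IFI27 (1.10 ± 0.19), MX1, an antiviral GTPase (1.00 ± 0.24), and LGALS3BP (0.73 ± 0.25, and 0.40 without 5-Aza-CdR replicate 1) were among the 6. The p53 targets were higher (median 0.17, adjusted p = 0.000364, and adjusted p = 0.346 with an estimated correlation), with TP53INP1 (0.61 ± 0.19) the 1 of 27 genes to rise with the block and 8 higher in that fit adjusted over the list alone.

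The replication list (median -0.13, adjusted p = 0.00032) and the cell cycle list (median -0.12, adjusted p = 0.00359) were lower, but not with an estimated correlation (adjusted p = 0.346 and adjusted p = 0.359 with an estimated correlation). Of their 31 and 38 genes 0 passed in either fit or adjusted over the list alone; MCM6 stood at -0.35 ± 0.16 and MKI67, the Ki-67 gene, at -0.39 ± 0.13. The oestrogen receptor targets were lower (median -0.22, adjusted p = 0.0205, and adjusted p = 0.346 with an estimated correlation), with 1 of 29 rising and 1 falling with the block, and 5 higher and 10 lower in that fit adjusted over the list alone. PGR (-0.45 ± 0.16) and PDZK1 (0.57 ± 0.19) did not pass over all probes. The brightest probe of GREB1 (-0.48 ± 0.17) did not pass either, and another of its probes did with the block (-0.52, adjusted p = 0.0173). These 5 shifts beyond the germline list were also lost without untreated replicate 1 (adjusted p = 0.0679 to 0.244) and without 5-Aza-CdR replicate 2 (0.0659 to 0.326).

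The other 20 lists did not shift without the block, and in that fit each had 0 to 2 genes higher and 0 lower when adjusted over the list alone. Of these, 3 passed with it: PRC2 and histone methyltransferases (median -0.07, adjusted p = 0.0549 without and 0.0444 with the block), cholesterol synthesis (median -0.11, 0.0568 and 0.0195) and leukocyte and stromal markers (median 0.04, 0.0711 and 0.0444). These blocked calls were lost with an estimated correlation (adjusted p = 0.632 with an estimated correlation for cholesterol synthesis and 0.55 for the other 2). Without the block all 3 passed without 5-Aza-CdR replicate 1 (0.0231, 0.00755 and 0.0356), the methyltransferases and the leukocyte markers without the filter (0.049 and 0.0472), and cholesterol synthesis under median scaling (0.0499) and without untreated replicate 2 (0.0147). Cholesterol synthesis and the leukocyte markers also passed without DZNep replicate 1 (0.0456 and 0.0477) and DZNep replicate 2 (0.0426 for each). No gene of the first 2 of these lists passed, with PHF19 at -0.41 ± 0.18 and DHCR7 at -0.28 ± 0.17, and 1 of 15 stromal and leukocyte markers rose with the block, CD14 at 0.44 ± 0.12. NNAT (0.55 ± 0.09, on 1 of its probes) and H19 (2.51 ± 0.53, and 1.55 without untreated replicate 1) rose among 16 imprinted genes (adjusted p = 0.0944 by camera, 0.0166 without untreated replicate 2), MUC1 (-0.63 ± 0.21, on 1 of its probes) fell and 1 rose among 21 luminal markers (0.0831, and 0.0456 and 0.0426 without DZNep replicate 1 or 2), and GPX1 rose and MT2A (-0.48 ± 0.17) fell among 23 metallothionein and oxidative stress genes (0.146). PHGDH (-0.79 ± 0.18) fell among 27 stress response genes (0.388), and COL12A1 (-0.42 ± 0.13, on 1 of its probes) fell and 1 gene rose among 36 adhesion and matrix genes (0.801), all with the block. In the remaining 12 lists 0 genes passed with the block. Camera gave adjusted p = 0.201 for oxidative phosphorylation, 0.243 for ribosomal proteins, 0.417 for glycolysis and hypoxia, 0.491 for the methionine cycle, 0.503 for apoptosis, 0.666 for nucleoside uptake, 0.67 for the unfolded protein response and 0.725 for developmental PRC2 targets. For 4 lists median, mean and test differed in sign: histone genes (median 0.05, adjusted p = 0.817), basal and mesenchymal markers (median -0.001, 0.855), DNA methylation machinery (median 0.0003, 0.903) and reference genes (median -0.02, 0.96, turned under median scaling).

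Among the enzymes read whatever their values, none passed after 5-Aza-CdR in either fit. DNMT1 stood at -0.19 ± 0.15, DNMT3A at 0.20 ± 0.16, DNMT3B at 0.31 ± 0.15, UHRF1 at -0.29 ± 0.17, EZH2 at -0.16 ± 0.33, SUZ12 at -0.04 ± 0.20, AHCY at -0.002 ± 0.23 and DCK at -0.08 ± 0.17. CDKN1A (0.19 ± 0.10), ESR1 (-0.48 ± 0.16, adjusted p = 0.055 with the block), TXNIP (0.14 ± 0.17), FBXO32 (0.48 ± 0.44) and TFF1 (0.11 ± 0.07) did not pass either.

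The direct comparison set DZNep against 5-Aza-CdR, at doses that cannot be matched because that of DZNep is not given. Of 45 measured germline and cancer-testis genes, 7 were lower after DZNep than after 5-Aza-CdR without the block and 15 with it, and 30 passed in neither fit. PAGE2B stood at -2.13 ± 0.25 (adjusted p = 0.0395) and PAGE5 at -1.68 ± 0.14 on 1 of its probes (0.0322), and outside the list GCNA stood at -2.04 ± 0.24 (0.0395) and CT83, a cancer-testis gene, at -1.64 ± 0.18 (0.0334). GPX1 (-2.43 ± 0.31, 0.0477) had the largest difference past the threshold in the fit without the block, on 1 of its 2 probes. The 5 genes with the lowest p among those higher after DZNep did not pass without the block (adjusted p = 0.0616 to 0.0716) and passed with it (0.000128 to 0.000249). Without 5-Aza-CdR replicate 2 all 5 passed without the block too (0.0247 to 0.0317), as did BCYRN1, FOXD4L1 and CSRP1 without DZNep replicate 2 (0.0417 to 0.0477) and all but CSRP1 with no further normalization (up to 0.0229). They were BCYRN1, a noncoding RNA with many related copies (1.80 ± 0.27), STRA6, a retinol transporter gene (1.36 ± 0.22), FOXD4L1, of a family of near-identical copies (1.26 ± 0.20), CSRP1 (1.03 ± 0.15) and FGFBP1 (0.80 ± 0.12).

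Without the block 28 probes passed, all lower after DZNep, for 22 genes, and 4133 had an unadjusted p under 0.05. With the block 4582 passed, 2133 higher and 2449 lower. The count of 28 became 0 without 5-Aza-CdR replicate 1 or DZNep replicate 1, 375 without 5-Aza-CdR replicate 2 and 167 without DZNep replicate 2, and on values with no further normalization it was 179 higher and 490 lower. The blocked count was 2224 without 5-Aza-CdR replicate 1 and 2074 without DZNep replicate 1, and its split moved from 46.6% higher to 36.1% under median scaling (1639 higher, 2895 lower) and to 21.4% with no further normalization (1154 higher, 4237 lower).

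The germline list was lower after DZNep than after 5-Aza-CdR (median -0.13, adjusted p = 3.43e-08; adjusted p = 0.346 with an estimated correlation), with 7 of 45 genes lower without the block, 14 when adjusted over the list alone and 15 with the block, among them DAZL, a germ cell RNA-binding protein gene (-0.95 ± 0.11). The interferon list was higher (median 0.22, 5.64e-05; adjusted p = 0.353 with an estimated correlation), with 19 of 42 genes higher and 2 lower with the block and 15 and 2 without it adjusted over the list alone. CXCL10 stood at 0.58 ± 0.10, whereas ISG20 was lower (-1.15 ± 0.26, and -0.75 without DZNep replicate 1). The replication list (median -0.28, 0.000199) and the cell cycle list (median -0.21, 0.000299) were lower, with 13 of 31 genes lower in the first and 13 of 38 lower and 1 higher in the second with the block, such as HMMR at -0.66 ± 0.18 (adjusted p = 0.346 with an estimated correlation for both). Adjusted over the list alone, 3 and 2 of them were lower without the block. The basal and mesenchymal list was higher (median 0.09, 0.00244; adjusted p = 0.346 with an estimated correlation), with 9 of 23 genes higher with the block and 7 without it adjusted over the list alone, such as the caveolin genes CAV1 (2.02 ± 0.41) and CAV2 (0.71 ± 0.17).

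The cholesterol list was lower (median -0.22, 0.00932; adjusted p = 0.353 with an estimated correlation), with 8 of 24 genes lower and 2 higher with the block, such as NSDHL at 0.43 ± 0.17 (0.24 without 5-Aza-CdR replicate 1), and did not pass without 5-Aza-CdR replicate 1 (0.0539). The stress response list was higher (median 0.14, 0.0341; adjusted p = 0.48 with an estimated correlation), with 6 of 27 genes higher and 1 lower with the block, such as ATF5 at -0.68 ± 0.20 (-0.39 without DZNep replicate 1), and did not pass without 5-Aza-CdR replicate 1 (0.252) or DZNep replicate 2 (0.196). The developmental PRC2 targets were higher (median 0.04, 0.0363, and adjusted p = 0.346 with an estimated correlation). They did not pass with the block (0.0567) or without the filter on dim probes (0.0883). Nor did they pass without untreated replicate 1, 5-Aza-CdR replicate 2 or DZNep replicate 1. With the block 8 of 61 genes were higher and 1 lower, among them MSX2 at 1.00 ± 0.23. CDKN2A, a tumour suppressor gene, stood at 0.78 ± 0.16 on 1 of its 3 probes, which was dim (mean log2 signal 7.42). Its other 2 probes, dimmer still, stood at -0.02 and 0.05 after DZNep against untreated, so a rise of this gene is uncertain. The oestrogen receptor targets (0.0568 without the block, 0.0444 with it; 4 of 29 higher, 12 lower) and the ribosomal proteins (0.0568 and 0.0206; 2 of 25 higher, 5 lower) passed with the block and not without it, and were lost with an estimated correlation (adjusted p = 0.59 with an estimated correlation and the block, for each). Without the block both passed under median scaling (0.027 and 0.00552), without the filter (0.0465 and 0.0438), without 5-Aza-CdR replicate 1 (0.0311 and 0.0121) and without DZNep replicate 2 (0.0395 and 0.0231), and the oestrogen receptor targets without untreated replicate 2 (0.0471). Adjusted over the list alone without the block, 2 cholesterol genes were lower, 0 stress response genes passed, 6 developmental genes were higher, 1 oestrogen receptor target was higher and 6 were lower, and 0 ribosomal protein genes passed. The other 16 lists passed camera in neither fit (adjusted p = 0.0831 to 0.826 without the block) and had 0 to 7 genes higher and 0 to 5 lower adjusted over the list alone. Median, mean and test differed in sign for 5 of these, the PRC2 and histone methyltransferase, leukocyte and stromal, unfolded protein response, metallothionein and glycolysis lists. With fry the germline list and the adhesion and matrix list passed in this comparison (adjusted p = 0.0494 for each).

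The responses to both drugs were then compared over 16766 genes. The growth-associated imprinted noncoding RNA H19 was higher with DZNep (1.75 ± 0.53) and with 5-Aza-CdR (2.51 ± 0.53), as was SALL4, a stem cell transcription factor gene (1.45 ± 0.22 and 1.37 ± 0.22). NCCRP1 stood at 1.16 ± 0.56 and 2.68 ± 0.56. SPANXC (1.25 ± 0.51 and 1.69 ± 0.51) and SPANXA2 (1.10 ± 0.49 and 1.65 ± 0.49) are near-identical copies of a cancer-testis family. These 5 had the largest shared rise among genes called with both drugs with the block. Their size, apart from SALL4, depended on single samples. Without untreated replicate 1 the DZNep and 5-Aza-CdR values of H19 were 0.79 and 1.55, those of SPANXC 0.49 and 0.93 and those of SPANXA2 0.39 and 0.93, and the DZNep value of NCCRP1 was 0.32. Without untreated replicate 2 the DZNep values were 2.71 (H19), 2.01 (SPANXC), 1.81 (SPANXA2) and 2 (NCCRP1). Without DZNep replicate 2 they were 0.67 (SPANXC), 0.52 (SPANXA2) and 0.47 (NCCRP1), and without DZNep replicate 1 they were 1.68 (SPANXA2) and 1.85 (NCCRP1). The 5-Aza-CdR value of H19 was 3.47 without untreated replicate 2. On the values with no further normalization all 5 genes passed in the limma fit without the block for both drugs. Their adjusted p was up to 0.00998 for DZNep and up to 0.000127 for 5-Aza-CdR. Lower with DZNep and higher with 5-Aza-CdR were GPER1, a membrane oestrogen receptor gene (-1.04 ± 0.34 and 1.18 ± 0.34, with another probe that passed for neither drug), MSMB (-0.60 ± 0.21 and 0.68 ± 0.21, with another probe that did not pass for 5-Aza-CdR), TYRP1 (-0.76 ± 0.19 and 0.58 ± 0.19), FBXO2 (-0.57 ± 0.21 and 0.96 ± 0.21) and STAT6, a transcription factor of interleukin 4 signalling (-0.66 ± 0.19 and 0.54 ± 0.19). With 1 DZNep sample left out the DZNep value of GPER1 ranged from -1.62 (replicate 2 left out) to -0.46 (replicate 1), and that of TYRP1 was -0.47 without replicate 1. STAT6 stood at 0.35 for 5-Aza-CdR without its replicate 1.

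With the block 68 genes were higher with both drugs, where independent lists would share 26.5, and 67 were lower with both, where they would share 9.21. Against 29.6 for independent lists, 13 genes were lower with DZNep and higher with 5-Aza-CdR, and 0 (8.25) the reverse. Unchanged groups simulated 100 times against the same 2 untreated samples shared on average 0.34 genes called higher and 0.31 called lower. In lists of the observed sizes, taken by moderated t with the block, they shared 131 higher and 51 lower, and 1.86 and 0.87 in the opposite classes. The simulated values leave out the effects and the independent lists the shared samples, so none of these counts measures a shared effect. Without the block the count in each class was 0, because limma called 0 genes for DZNep at that threshold. Log2 fold changes correlated at r = 0.383 across genes with a covariance of 0.0227. The simulated groups gave a mean r of 0.5 and a mean covariance of 0.00462, and the covariances differed by 0.018. The untreated samples cannot be divided into sets of at least 2, so part of the excess in the counts may come from the shared samples. With 1 untreated sample on each side and none shared, r was 0.352 for DZNep replicate 1 with 5-Aza-CdR replicate 2 (rho = 0.314, covariance 0.0249) and 0.259 for the reverse (rho = 0.169, covariance 0.0155). In the fit without the block r was 0.0961 without 5-Aza-CdR replicate 2 and 0.6 without untreated replicate 2.

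**Figure D4:**
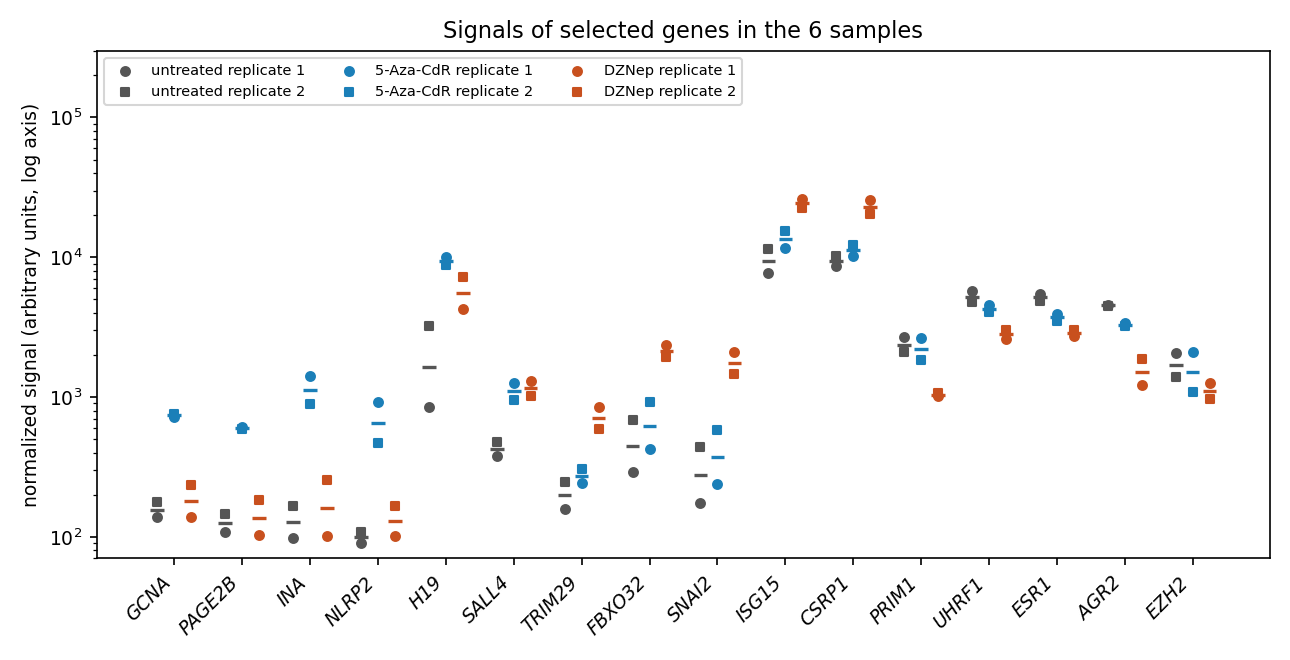
Normalized signals (arbitrary units, log axis) of 16 genes in the 6 samples, with bars at the geometric mean of each group of 2. GCNA lies at 724 and 759 in the 5-Aza-CdR samples and between 138 and 236 in the other 4, and AGR2 lies at 1210 and 1863 in the DZNep samples and between 3224 and 4591 in the other 4.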

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

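The normexp setting with offset 16, the setting with probes above the median signal, all settings that combine the block with another change and the comparisons on bead codes pooled over both files were chosen after seeing the data; the others were planned. The planned detection filter was not run. The cause of the changes below was not tested, except that settings with fewer samples, genes or groups differ by construction. Signal over background limits dim genes, whose changes are understated.

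Counts of called probes are given in the order DZNep against untreated, 5-Aza-CdR against untreated and DZNep against 5-Aza-CdR, against 0, 55 and 28 in the main setting. The fit with the replicate number as a block gave 5076, 438 and 4582, and the values with no further normalization 734, 104 and 669. Median scaling moved the last count to 49, normexp to 15 (offset 50) and 0 (offset 16), no filter to 53 and probes above the median to 17. The plain t-test, the fit without the intensity trend and gene means gave 0 in each comparison, and only the groups compared gave 609 for DZNep. Leaving out each sample gave 0 to 635, 0 to 75 and 0 to 375. Within the blocked fit, a minimum change of 1 gave 380, 76 and 307, leaving out each sample gave 1240 to 6171, 147 to 1198 and 2074 to 5865, and other settings stayed within 1.5 times the counts, at 4867 to 5714, 356 to 643 and 4475 to 5391. On the bead codes DZNep against untreated went from 0 of 2347 codes to 209 with the block, 31 on the first and 7 on the second file alone and 176 with all files and the sample as a random block.

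Of 78 list tests 23 passed in the main setting, 0 with an estimated correlation and 8 with fry. All 23 also passed under median scaling, 22 with the block, 21 without the filter, 6 with fry and 16 to 22 with each sample left out, and none turned. With the block 129 of 174 values of named genes newly passed and 45 kept their side, and of the lists 7 changed side, each given with its comparison. The counts of list members and of genes called with both drugs changed too, as given above. The correlation between the drugs, 0.383, ranged from 0.0961 to 0.6 with each sample left out, and was 0.385 under median scaling.

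Camera's sign turned for lists that passed in neither setting. Adjusted p was then 0.839 (histone genes, DZNep), 0.532 (oxidative phosphorylation, DZNep), 0.989 and 0.738 (reference genes, DZNep and 5-Aza-CdR) under median scaling and 0.91 without the filter (DNA methylation machinery, 5-Aza-CdR). With fry it was 0.0983 and 0.825 (histone genes, DZNep and 5-Aza-CdR), 0.87 (DNA methylation machinery, 5-Aza-CdR) and 0.84 (basal and mesenchymal markers, 5-Aza-CdR). With each sample left out the sign of some DZNep lists turned at least once, with adjusted p from 0.198 to 0.917 (PRC2), 0.831 to 0.988 (histone), 0.356 to 0.991 (imprinted) and 0.248 to 0.962 (reference). For 5-Aza-CdR these ranges were 0.558 to 0.991 (DNA methylation machinery), 0.0561 to 0.857 (stress response), 0.0838 to 0.72 (nucleoside uptake), 0.686 to 0.991 (reference), 0.472 to 0.919 (basal), 0.224 to 0.996 (apoptosis), 0.406 to 0.982 (developmental) and 0.651 to 0.979 (histone).

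The genes that turned sign passed neither in the main setting nor in the one named. With no further normalization DNMT3A stood at -0.0532 (DZNep) and AHCY at 0.00821 (5-Aza-CdR), which was 0.00698 under median scaling, and on gene means CDKN1A stood at 0.301 and PFKP at 0.214 (DZNep). With each sample left out the DZNep values ranged from -0.167 to 0.436 (AHCY), -0.0228 to 0.0394 (DNMT3A), -0.296 to 0.0417 (SUZ12), -0.117 to 0.0514 (CDKN1A) and -0.195 to 0.0497 (DNMT3B), and the 5-Aza-CdR values from -0.239 to 0.234 (AHCY), -0.0698 to 0.47 (DNMT3A), -0.645 to 0.316 (EZH2), -0.231 to 0.143 (SUZ12) and -0.137 to 1.09 (FBXO32).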

Other observations

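The tests of the background, of compression, of the shared untreated samples, of gene copies as the whole cause, of the keratin family and of the shift between replicate numbers were chosen only after their results or related ones had been seen; the tests of a mixture, of low starting values and of gene copies were set before.

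Of 39 keratin genes outside the fixed lists, 11 rose and 0 fell after DZNep in the fit with the replicate number as a block. KRT16, a keratin of stressed and regenerating epidermis, stood at 2.52 ± 0.56 on the log2 scale (SE, n = 2 per group), KRT6C at 2.48 ± 0.52, KRT9, a keratin of palm and sole skin, at 1.82 ± 0.47, KRT4 at 0.70 ± 0.16 and KRT10 at 0.69 ± 0.19. All 5 passed in that fit (limma adjusted p = 0.000109 to 0.00468) and none without it (0.075 to 0.146). KRT16 and KRT6C have near-identical copies, so the copy is uncertain. Among 203 families of genes with a shared symbol root, of at least 10 tested genes each and outside the lists, the keratins shifted by camera (median 0.13, adjusted p = 0.00135 over all families and comparisons, 0.00805 with the block, where adjusted p = 0.999 with an estimated correlation). A hypothesis is that keratins respond to DZNep as a family, but the adjusted p was 0.981 with an estimated correlation, so this stays open.

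DZNep changes were smaller in replicate 2, and the untreated and 5-Aza-CdR replicate 2 samples lay toward the DZNep profile. In 792 called genes with signals of at least 20 times the background in both groups, the summed change within replicate 2 was 0.629 of that within replicate 1 (95% bootstrap interval 0.617 to 0.641), which argues against the higher background of the replicate 2 arrays as the cause. Compression of all changes on those arrays stays open, because the ratio was 0.745 in genes called for 5-Aza-CdR and 0.631 in all genes called for DZNep, a difference of 0.114 (0.0907 to 0.138), as does untreated RNA mixed into DZNep replicate 2, because raised genes would need a share of 0.429 and lowered genes 0.3, a difference of 0.129 (0.104 to 0.151). Across 16766 genes the difference between 5-Aza-CdR replicate 2 and replicate 1 correlated at r = 0.295 (0.289 in bright genes) with the DZNep change within replicate 1, which uses none of the same samples, so a hypothesis is that a difference between the replicate numbers follows the DZNep changes (genes are not independent replicates). The labels give no difference between the numbers, and no biological explanation was tested.

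Genes raised by 5-Aza-CdR started at low signals more often than genes raised by DZNep. Of 70 genes raised at least 2-fold within replicate 1, 47 (67.1%, Clopper-Pearson interval 54.9 to 77.9) lay below the median of tested genes in untreated replicate 2. That sample did not enter their fold change, but the signal filter and the choice of a gene's probe used all 6 samples. Of 277 genes raised as much by DZNep, 54 lay below that median (19.5%, interval 15.0 to 24.7). Fisher's exact p was 1.82e-16 over genes raised by 1 drug alone (two-sided, genes not independent). For chance low values in untreated replicate 1 a bound of 55% had been set beforehand. They stay open, since the interval reaches that bound and the share that chance would leave was not simulated. Without the near-identical cancer-testis families the share was 66.1% (37 of 56 genes, 52.2 to 78.2), and 46.4 percentage points (95% bootstrap interval 32.7 to 59.0) above that of DZNep-raised genes, so shared copies are not the whole cause of the difference, and a part from them stays open. The drug's action on silent genes, as a biological explanation, stays open and was not tested.

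The responses to the drugs correlated. With different untreated samples on each side the lower of the 2 correlations was 0.259, so noise of a single shared untreated sample is not the whole cause. The labels do not say that the 2 untreated samples are separate cultures. A deviation common to both would enter either side and stays open. In the fit without the block r was 0.0961 without 5-Aza-CdR replicate 2, but that fit sets 5-Aza-CdR replicate 1 against the mean of both untreated samples, so the difference between the replicate numbers enters it. The correlation of 0.259 does not use 5-Aza-CdR replicate 2 either.

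In every replicate 2 sample 8 probes, among them those of LIPT1 and TAP2, had signals of 8.8 to 11.2, against 64.8 to 636.2 in the replicate 1 samples.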
